A study of Mus musculus with 40 samples.

How the data were processed

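Gene expression was measured on 39 Affymetrix mouse arrays of 45101 probe sets, hybridized with poly(A) RNA of 1-cell and 2-cell B6D2 embryos. The 10 groups are fertilized, SCNT and parthenogenetic embryos at both stages, and fertilized and SCNT embryos with α-amanitin at both stages. Each holds 4 arrays, except that the values of replicate 2 of the untreated 1-cell SCNT embryos are empty, so that group has 3, and 39 of 40 planned arrays were used. The letter A before the replicate number was read as α-amanitin. The labels spell this out for 7 of the 8 SCNT samples with that letter, and for the fertilized ones it rests on the same code and on the text on the design. The labels name MEMα as culture medium for SCNT embryos and KSOM for 1 fertilized sample, and no medium for the other fertilized and the parthenogenetic samples, so medium cannot be separated from origin.

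The deposited values are probe set intensity on a linear scale, globally scaled by the authors with software that the sources used here do not name. The 64 control probe sets were set aside. The rest were taken as log2 of the value plus 6.9, the 20th percentile of all values. Array medians ranged from 4.916 to 5.739, a range of 0.822 that exceeded the limit of 0.5 fixed for using the values as deposited, so the log2 values were quantile normalized. Probe sets above the overall median of 5.34 on at least 4 arrays were kept, 31153 in all. Of the probe sets, 34945 are listed with 1 gene, 932 with several and 9160 with none, and only those with 1 gene were used, 25931 of those kept. The probe set with the highest mean stood for each gene, which gave 14916 genes.

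Group means were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend, on 29 residual degrees of freedom. The 15 comparisons of groups and 3 interactions were read from that fit, 2-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. Interactions are the SCNT minus fertilized difference of the amanitin effect at each stage and of the change between the stages. Gene lists, 23 in number, were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, and adjusted over the lists of a comparison. Camera calls named in the text hold with the estimated correlation unless its adjusted p is given. Single measures, such as controls and list means per array, were compared by exact permutation tests. Their smallest p is 0.0286 with 4 or 3 arrays against 4. Groups of 4 arrays each fail to overlap by chance in 2 of 70 arrangements, and 3 against 4 in 2 of 35. Overlaps of calls are given only for comparisons that share no array, beside the count for independent calls.

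The gene lists, comparisons, thresholds and the rule for naming genes were fixed before the data were examined. The rule gives per comparison the 5 largest called increases and 5 largest called decreases among genes with non-overlapping arrays and without predicted-gene symbols, up to 4 called and 2 other members of each list described, and 21 genes named beforehand. Of these 21, 6 (Zscan4c, Zscan4d, Nanog, H19, Snrpn and Gapdh) were not measured by the genes tested. The text names part of what the rule gives, and leaves out some genes whose call rested on single arrays or on the choice of probe set, a selection made after their values were seen. The lists cover oocyte, 2-cell stage, ribosome biogenesis, ribosomal protein, translation, splicing, proteasome, RNA polymerase II, oxidative phosphorylation, glycolysis, cumulus, cytoskeleton, spermatid, blood, DNA methylation, histone modifier, pluripotency, imprinted, heat-shock, p53, cell-cycle and transporter genes.

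Transcription-dependent genes were chosen on 2 untreated and 2 amanitin arrays of fertilized 2-cell embryos, as called genes at least 2-fold lower with amanitin. The 4 untreated SCNT arrays were then compared with the other 2 untreated fertilized arrays, over all 6 divisions. Replicate numbers do not pair samples: over 20 pairs of groups the correlation of residuals with the same number ran from -0.0627 to 0.113, and 21 of 76 samples matched their own number best. Replicates of a group correlated at 0.9397 to 0.9797 across genes. The pipeline was tested on simulated data with 200 planted genes among those of a 2-cell comparison. It recovered 17.91%, 43.28% and 92.42% of changes of 0.5, 1 and 2 log2 units, and 6.422% of its 109 calls were false. On arrays, signal over background limits what dim probe sets can show, and a probe set below the filter is not detectable here and not absent.

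Alternatives were no filter, a filter on the mean, values as deposited, median centring, constants at the 5th and 40th percentile (1.8 and 22.1), the mean of a gene's probe sets, no trend, array weights, only the compared arrays, a replicate block, and each array left out in turn. Leaving out fertilized 1-cell replicate 1 and SCNT 1-cell amanitin replicate 4 together was added after the data were seen. Hybridization and poly(A) control transcripts and the 18S probe set were summarized per array as controls.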

Results

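The arrays cover mouse B6D2 embryos at the 1-cell and 2-cell stages that were fertilized, made by somatic cell nuclear transfer (SCNT) from cumulus cells, or parthenogenetic. Fertilized and SCNT embryos were also cultured with α-amanitin, an inhibitor of RNA polymerase II. On the 39 arrays the first 3 principal components held 52.2%, 16.4% and 6.38% of the variance. Component 1 ran from 59.21 to 138.5 on the untreated 2-cell arrays and from -55.21 to -42.28 on the others. Values in parentheses after a gene are log2 differences with their standard error (SE), and adjusted p-values come from limma over 14916 genes. Genes given first in each comparison had arrays of the 2 groups that did not overlap. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between samples. In 94 of 255 differences between groups given for genes, a group lay under the overall median of 5.34, where the added constant sets part of the difference. Low and high constants are those at the 5th and 40th percentile. The probe set with the highest mean was picked anew with each, so a value can also change through another probe set.

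**Figure D1:**
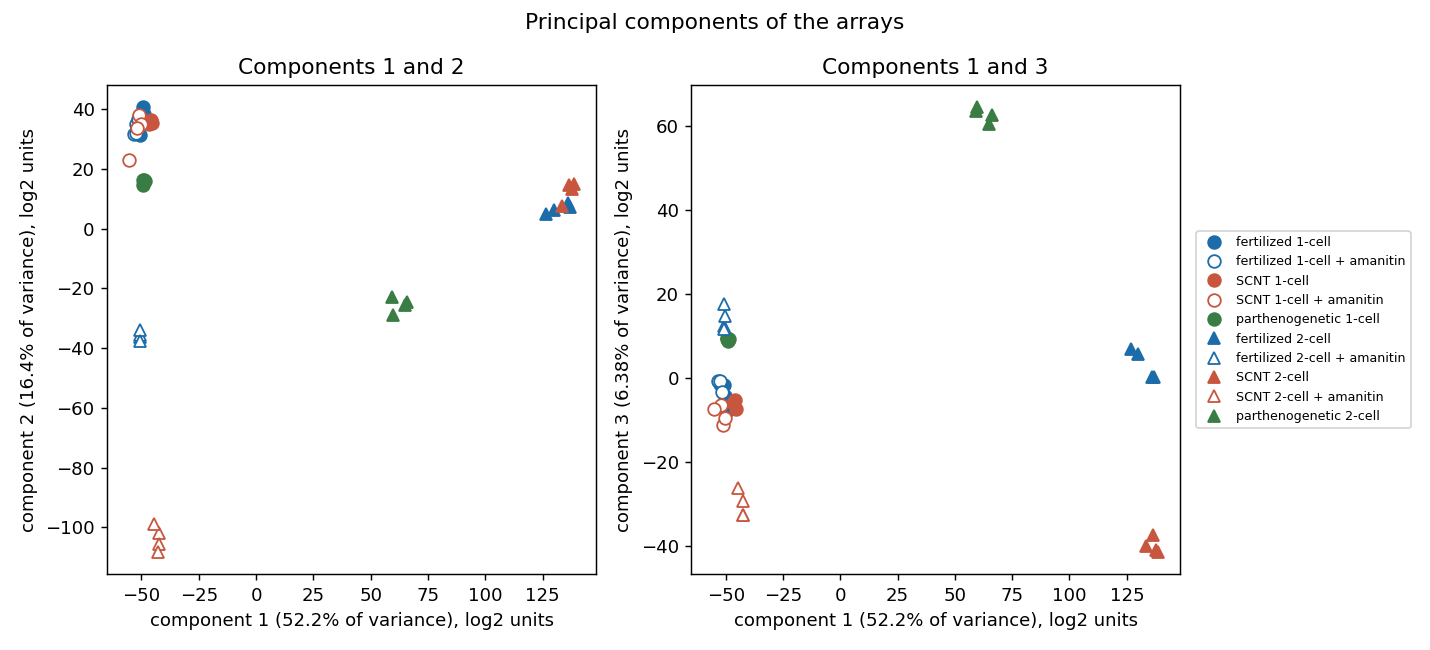
Scores of the 39 arrays on principal components 1 to 3 of the log2 intensities, 1 point per array, colored by origin, with circles for 1-cell and triangles for 2-cell embryos and open symbols for amanitin. The 4 parthenogenetic 2-cell arrays lie at 60.52 to 64.46 on component 3, above every other array.

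Between the 1-cell and 2-cell stages, fertilized embryos gained 2-cell stage and ribosomal protein transcripts and lost many oocyte transcripts. Crxos, a homeobox gene of early embryos, went to 12.41 ± 0.20 (SD, n = 4) against 3.62 ± 0.74 (n = 4) in log2 units (a rise of 4.75 or 7.60 with the low or high constant). Also higher were Calcoco2 (7.96, SE 0.40), an autophagy receptor, Btbd18 (7.83, SE 0.34) and Ppp2cb (7.77, SE 0.32), a catalytic subunit of protein phosphatase 2A. Lower were Crabp2 (-6.64, SE 0.27), a retinoic acid binding protein, Zfp57 (-6.63, SE 0.37), a zinc finger protein that guards imprints, Pabpn1l (-5.94, SE 0.24), an oocyte poly(A) binding protein, and Glrx (-5.86, SE 0.26), a glutaredoxin (adjusted p at most 9.41e-19). Of the genes fixed beforehand, Zfp352 (4.59, SE 0.25), Eif1a (2.17, SE 0.28), Cdkn1a (2.53, SE 0.24) and Hspa1a (2.08, SE 0.29) rose, while Mos (-3.91, SE 0.24), a kinase of meiosis, Dnmt1 (-1.93, SE 0.21), the maintenance DNA methyltransferase, and Gdf9 (-1.89, SE 0.08), an oocyte growth factor, fell (adjusted p at most 5.3e-08).

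Among oocyte and maternal-effect transcripts 31 of 37 measured members fell, 2 rose and 4 were not called (31 and 2 adjusted over the list alone), with median -2.31, camera adjusted p = 3.97e-13. Examples are Ooep (-4.64, SE 0.12) of the subcortical maternal complex, Lhx8 (-3.41, SE 0.09), an oocyte transcription factor, and Zar1 (-3.80, SE 0.13). Of the 2-cell stage activated genes 22 of 28 measured members rose, 5 fell and 1 was not called (22 and 5 adjusted over the list alone) (median 2.38, camera adjusted p = 1.64e-07). Examples are Obox6 (7.68, SE 0.29) and Pramel7 (7.54, SE 0.28). Cytosolic ribosomal proteins moved together, since 40 of 44 measured members rose, 0 fell and 4 were not called (40 and 0 adjusted over the list alone) (median 3.03, camera adjusted p = 1.64e-21). These include Rpl41 (5.65, SE 0.18) and Rps18 (4.85, SE 0.16). In ribosome biogenesis 50 of 63 measured members rose, 4 fell and 9 were not called (50 and 4 adjusted over the list alone) (median 1.57, camera adjusted p = 7.65e-15). Among them are Polr1c (5.33, SE 0.18), a subunit of RNA polymerases I and III, and Tsr1 (4.03, SE 0.14), a 40S maturation factor. Pluripotency and early lineage factors also went up: 20 of 31 measured members rose, 6 fell and 5 were not called (20 and 6 adjusted over the list alone) (median 1.06, camera adjusted p = 0.000667). Examples are Fbxo15 (5.23, SE 0.17), Dppa4 (4.46, SE 0.19) and Klf5 (3.60, SE 0.18). In the RNA polymerase II machinery 28 of 48 measured members rose, 8 fell and 12 were not called (28 and 8 adjusted over the list alone) (median 0.58, camera adjusted p = 0.00128). Cdk9 (3.45, SE 0.15), the elongation kinase, went up and Gtf2b (-2.72, SE 0.11), the factor TFIIB, down. In all, limma called 8954 of 14916 genes (3849 higher, 5105 lower, 6002 by at least 2-fold). The 18S probe set fell from 13.15 (SD 0.19) to 9.50 (SD 0.21) in fertilized, from 13.47 (SD 0.15) to 10.14 (SD 0.35) in SCNT and from 12.98 (SD 0.14) to 11.45 (SD 0.05) in parthenogenetic embryos.

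In SCNT embryos the change between the stages called 9058 of 14916 genes (3920 higher, 5138 lower, 6392 by at least 2-fold), and in parthenogenetic embryos 7328 of 14916 genes (3238 higher, 4090 lower, 3906 by at least 2-fold). Crxos rose by 8.75 (SE 0.39) in SCNT and 7.24 (SE 0.36) in parthenogenetic embryos, but by 2.19 and 2.55 with the low constant. In that order, Obox6 rose (7.82, SE 0.31, and 6.60, SE 0.29) and Zfp57 fell (-6.19, SE 0.40, and -4.49, SE 0.37). All had adjusted p at most 9.44e-17 and 3.06e-13. Crabp2 (-6.41, SE 0.30) fell in SCNT embryos, and in parthenogenetic embryos Prmt6 (7.51, SE 0.41), Mt1 (7.08, SE 0.28) and Hspa1a (5.41, SE 0.29) rose (adjusted p at most 1.64e-18). Fertilized and SCNT embryos, which share no array, had 3023 genes higher and 4165 lower at the 2-cell stage in both, against 1010 and 1760 for independent calls, and 179 moved in opposite directions. For fertilized and parthenogenetic embryos the numbers were 2298 and 3279 against 836 and 1400, with 388 opposite.

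Of the oocyte transcripts, 34 of 37 measured members fell, 1 rose and 2 were not called (34 and 1 adjusted over the list alone) in SCNT embryos (median -2.23, camera adjusted p = 5.4e-15), and 25 of 37 measured members fell, 1 rose and 11 were not called (25 and 1 adjusted over the list alone) in parthenogenetic embryos (median -0.75, camera adjusted p = 9.89e-08). The 2-cell stage genes went the other way: 20 of 28 measured members rose, 3 fell and 5 were not called (20 and 3 adjusted over the list alone) in SCNT embryos (median 1.72, camera adjusted p = 1.61e-05), and 22 of 28 measured members rose, 2 fell and 4 were not called (22 and 2 adjusted over the list alone) in parthenogenetic embryos (median 3.58, camera adjusted p = 6.84e-15). Among proteasome subunits 23 of 37 measured members rose, 6 fell and 8 were not called (24 and 6 adjusted over the list alone) in SCNT embryos (median 1.08, camera adjusted p = 0.000347). Among them are Psmb5 (3.98, SE 0.23) and Psma3 (2.91, SE 0.16). In parthenogenetic embryos 18 of 39 measured members rose, 5 fell and 16 were not called (19 and 5 adjusted over the list alone) of the p53 and stress-response genes (median 0.30, camera adjusted p = 0.0025), led by Mt2 (5.83, SE 0.17) and Sesn2 (4.36, SE 0.21). The split of the calls moved with the scaling. As deposited it was 4572 higher and 3505 lower in parthenogenetic and 4546 and 4543 in SCNT embryos. After median centring it was 2122 and 5595, and 3395 and 5735, in that order. The median difference of all genes (as tested, as deposited, median centred) was -0.04, 0.21, -0.26 in parthenogenetic and -0.14, 0.07, -0.27 in SCNT embryos. In fertilized ones it was -0.13, -0.04, -0.19, so these changes are relative to that shift. The untreated 1-cell SCNT arrays lack the poly(A) control transcripts (mean log2 4.03, SD 0.09), which the 2-cell SCNT arrays hold (10.13, SD 0.48).

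Amanitin in fertilized 2-cell embryos took Prmt6 (-7.84, SE 0.41), Wdr77 (-7.80, SE 0.28), a partner of the arginine methyltransferase PRMT5, Ppat (-7.71, SE 0.22), the first enzyme of purine synthesis, Calcoco2 (-7.69, SE 0.40) and Crxos (-7.66, SE 0.36) down. Ppat stood at 3.71 ± 0.42 (SD, n = 4) against 11.42 ± 0.11 (n = 4) with and without amanitin, near background with it, and had a difference of -8.49 or -6.59 with the low or high constant, and Crxos -4.86 or -7.00. Transcripts that were higher under amanitin included Nobox (4.81, SE 0.28), an oocyte homeobox gene, Zfp383 (5.14, SE 0.20), Insm1 (4.74, SE 0.23) and Aplf (4.80, SE 0.22), a DNA repair factor (adjusted p at most 2.28e-18). Zfp352 (-4.63, SE 0.25), Hspa1a (-2.88, SE 0.29), Hspa1b (-2.71, SE 0.18) and Eif1a (-1.75, SE 0.28) fell, while Mos (2.16, SE 0.24) and Gdf9 (1.06, SE 0.08) were higher (adjusted p at most 6.14e-07).

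Of the 2-cell stage activated genes 22 of 28 measured members fell, 4 rose and 2 were not called (22 and 4 adjusted over the list alone) (median -3.06, camera adjusted p = 3.7e-09). Examples are Obox6 (-7.47, SE 0.29) and AF067063 (-5.97, SE 0.15). Ribosome biogenesis went down nearly as a whole: 59 of 63 measured members fell, 0 rose and 4 were not called (59 and 1 adjusted over the list alone) (median -2.52, camera adjusted p = 3.38e-26). These include Surf6 (-7.11, SE 0.21) and Nmd3 (-4.25, SE 0.13), the 60S export adaptor. Cytosolic ribosomal proteins did likewise, as 41 of 44 measured members fell, 1 rose and 2 were not called (41 and 1 adjusted over the list alone) (median -3.14, camera adjusted p = 2.57e-22). Among them is Rpl7 (-5.00, SE 0.16). Oocyte transcripts stood higher with amanitin than without (median 1.49, camera adjusted p = 7.58e-08). Of 37 measured, 30 were higher, 3 lower and 4 not called (30 and 3 adjusted over the list alone). Their median change from the 1-cell stage under amanitin was -0.56. Examples are Dazl (4.12, SE 0.14), an RNA binding protein of germ cells, and Ooep (3.36, SE 0.12). Of the pluripotency and early lineage factors 19 of 31 measured members fell, 5 rose and 7 were not called (19 and 5 adjusted over the list alone) (median -0.90, camera adjusted p = 0.000324). These include Dppa4 (-5.59, SE 0.19) and Fbxo15 (-4.74, SE 0.17). The test called 9596 of 14916 genes (5753 higher, 3843 lower, 6476 by at least 2-fold). The 18S probe set, outside the genes tested, measured 13.13 (SD 0.14) with amanitin and 9.50 (SD 0.21) without.

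In SCNT 2-cell embryos amanitin also lowered Ppat (-8.05, SE 0.22), Pramel7 (-7.94, SE 0.28), Psat1 (-7.89, SE 0.38), an enzyme of serine synthesis, and the cathepsins Ctsc (-7.94, SE 0.37) and Ctsl (-7.89, SE 0.17). Higher under amanitin were Arhgef16 (4.67, SE 0.28), Slc41a3 (4.39, SE 0.49), a magnesium transporter, and Bet1 (3.83, SE 0.23), a protein of vesicle transport (adjusted p at most 1.93e-10). Zfp352 (-4.23, SE 0.25), Hspa1a (-4.57, SE 0.29), Cdkn1a (-2.96, SE 0.24) and Xist (-1.80, SE 0.18), the RNA of X inactivation, fell (adjusted p at most 1.72e-11). Of the 2-cell stage genes 23 of 28 measured members fell, 1 rose and 4 were not called (23 and 1 adjusted over the list alone) (median -3.19, camera adjusted p = 4.03e-09). In ribosome biogenesis 60 of 63 measured members fell, 1 rose and 2 were not called (60 and 1 adjusted over the list alone) (median -3.10, camera adjusted p = 5.19e-24). Among them are Nolc1 (-5.50, SE 0.14) and Nip7 (-5.06, SE 0.14). Of the splicing factors 52 of 63 measured members fell, 7 rose and 4 were not called (52 and 7 adjusted over the list alone) (median -2.11, camera adjusted p = 2.42e-15). Examples are Tra2a (-6.47, SE 0.20) and Srsf1 (-4.82, SE 0.16). Proteasome subunits fell too, as 33 of 37 measured members fell, 3 rose and 1 was not called (33 and 3 adjusted over the list alone) (median -2.76, camera adjusted p = 1.59e-13). These include Psmd14 (-5.36, SE 0.16). Of the oxidative phosphorylation genes 59 of 73 measured members fell, 7 rose and 7 were not called (59 and 7 adjusted over the list alone) (median -1.92, camera adjusted p = 3.44e-13). Among them is Atp5g1 (-7.12, SE 0.21). Oocyte transcripts were higher with amanitin (median 1.80, camera adjusted p = 2.77e-09). Of 37 measured, 33 were higher, 2 lower and 2 not called (33 and 2 adjusted over the list alone). An example is Zp2 (2.14, SE 0.10).

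The test called 10327 of 14916 genes (5903 higher, 4424 lower, 7512 by at least 2-fold) in SCNT embryos, where the 18S probe set measured 13.49 (SD 0.24) with amanitin and 10.14 (SD 0.35) without, and the hybridization controls 10.88 (SD 0.19) and 9.58 (SD 0.15). With no array in common, the amanitin comparisons of fertilized and SCNT 2-cell embryos shared 4325 higher and 3154 lower genes, against 2280 and 1140 for independent calls, and 568 were opposite. The median difference of all genes (as tested, as deposited, median centred) was 0.27, 0.23, 0.23 in fertilized and 0.28, 0.24, 0.19 in SCNT embryos. The amanitin effects are relative to that shift. Transcription-dependent genes, at least 2-fold lower under amanitin on 2 of 4 arrays per fertilized 2-cell group, numbered 2805 to 2905 over 6 divisions. Their median difference of untreated SCNT embryos minus the other 2 untreated fertilized arrays ran from -0.11 to -0.02 (mean -0.06, SD 0.03 over divisions). Of them, 16.3% to 18.1% were lower and 9.7% to 13.2% higher. The median of all genes was -0.05 with all 4 fertilized arrays, near that of the set.

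The amanitin effect itself differed between the origins at the 2-cell stage for 5807 of 14916 genes (2657 higher, 3150 lower, 3730 by at least 2-fold), as tested by the interaction (SCNT effect minus fertilized effect). Among the most negative were Mrpl11 (-6.31, SE 0.39), a mitochondrial ribosomal protein, Tardbp (-5.90, SE 0.18), an RNA binding protein, Ube2d1 (-5.48, SE 0.36), a ubiquitin-conjugating enzyme, Wdr61 (-5.42, SE 0.28) and Psmb3 (-5.24, SE 0.24), a proteasome subunit. Among the most positive were Mep1b (5.29, SE 0.68), a metalloprotease, Cltrn (4.13, SE 0.38), Krt28 (3.93, SE 0.52), a keratin, and Nxt2 (3.91, SE 0.23), an mRNA export factor (adjusted p at most 5.3e-08). Zp3 (2.13, SE 0.16), a zona pellucida protein, had an effect of -1.12 in fertilized and 1.01 in SCNT embryos. Others were Dnmt3b (-1.81, SE 0.20), Xist (-1.38, SE 0.26) and Hspa1a (-1.69, SE 0.41) in the interaction (adjusted p at most 0.000903).

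Proteasome subunits differed as a group in that effect: 33 of 37 measured members were negative, 0 positive and 4 not called (34 and 0 adjusted over the list alone) (median -1.31, camera adjusted p = 1.48e-15). These include Psma7 (-3.67, SE 0.26) and Psmb6 (-2.80, SE 0.20). In oxidative phosphorylation 59 of 73 measured members were negative, 2 positive and 12 not called (60 and 2 adjusted over the list alone) (median -1.60, camera adjusted p = 2.21e-17). Among them are Atp5g1 (-4.33, SE 0.30) and Cox5a (-1.81, SE 0.12). Splicing factors went the same way, since 39 of 63 measured members were negative, 3 positive and 21 not called (41 and 3 adjusted over the list alone) (median -0.89, camera adjusted p = 3.13e-12). Examples are Lsm3 (-4.45, SE 0.15) and Snrpd3 (-4.30, SE 0.20). Of the translation factors 23 of 38 measured members were negative, 6 positive and 9 not called (24 and 7 adjusted over the list alone) (median -0.82, camera adjusted p = 1.07e-05). These include Eef1b2 (-3.19, SE 0.19). Of the cell-cycle and mitosis genes 33 of 65 measured members were negative, 5 positive and 27 not called (33 and 6 adjusted over the list alone) (median -0.47, camera adjusted p = 0.000161). Among them is Cenpa (-3.24, SE 0.15), the centromeric histone. The poly(A) controls stood at 11.86 (SD 0.24) on the SCNT amanitin arrays, 10.13 (SD 0.48) on the untreated SCNT arrays, and 8.72 (SD 0.17) and 9.06 (SD 0.75) on the 2 fertilized groups.

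**Figure D2:**
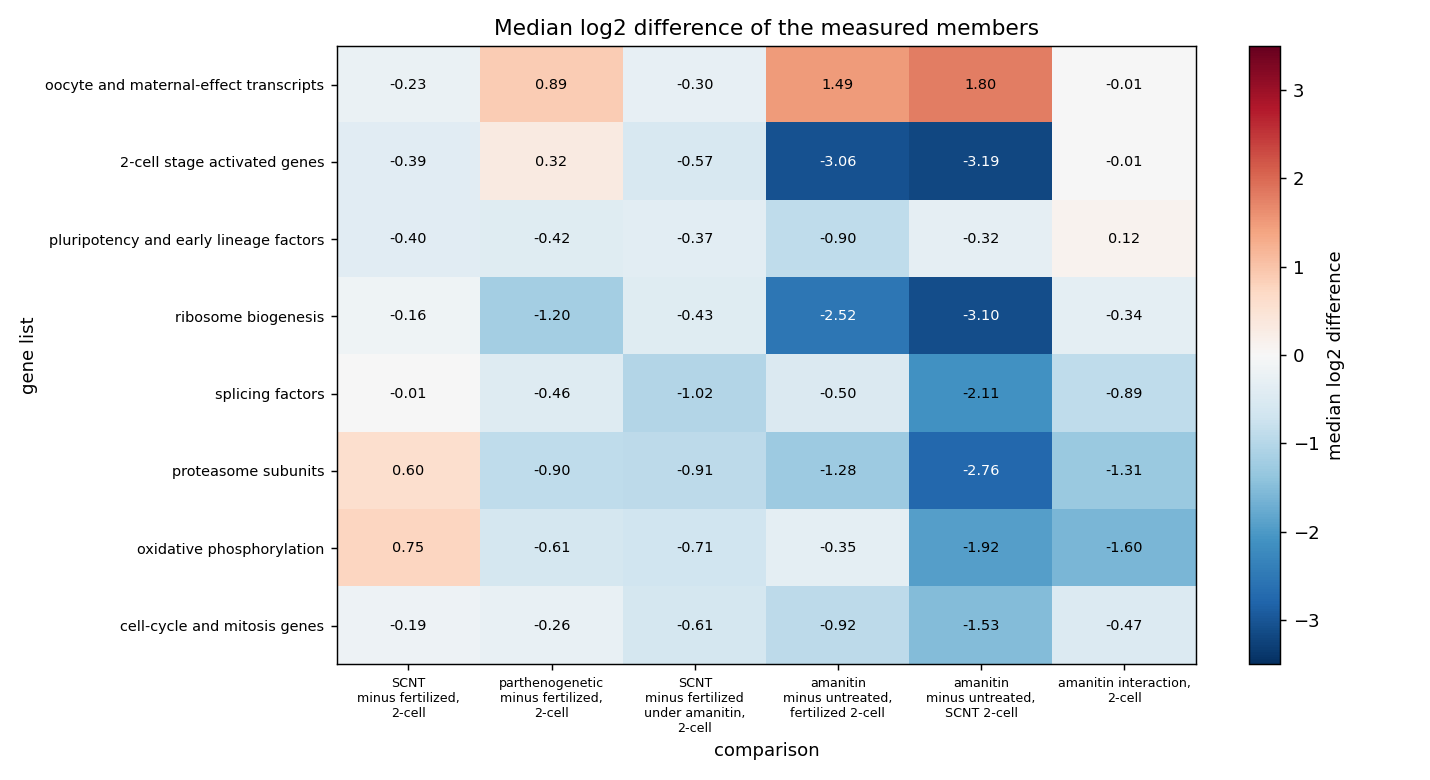
Median log2 difference of the measured members of 8 gene lists (vertical axis) in 6 comparisons of 2-cell embryos (horizontal axis), with the value printed in each cell. Proteasome subunits have a median of 0.60 between untreated SCNT and fertilized embryos and -0.91 under amanitin, and the interaction medians of oocyte transcripts and of 2-cell stage genes, both -0.01, become 0.02 and 0.22 with the values as deposited.

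In fertilized 1-cell embryos under amanitin Mt1 (-2.06, SE 0.28) and Mt2 (-1.64, SE 0.17), metallothioneins, Usp17la (-1.83, SE 0.24), a deubiquitinase of the 2-cell stage list, Zfp352 (-1.23, SE 0.25) and Ldha (-1.41, SE 0.33), a lactate dehydrogenase subunit, fell, and B3gnt4 (1.87, SE 0.36) and Col9a3 (1.66, SE 0.40), a collagen, were higher (adjusted p at most 0.00762). The test called 900 of 14916 genes (535 higher, 365 lower, 121 by at least 2-fold). Of the 2-cell stage genes 4 of 28 measured members fell, 0 rose and 24 were not called (4 and 0 adjusted over the list alone) (median -0.14, camera adjusted p = 0.0324, adjusted p = 0.14 with an estimated correlation). For translation factors 6 of 38 measured members fell, 0 rose and 32 were not called (10 and 1 adjusted over the list alone) (median -0.18, camera adjusted p = 0.000503), but after median centring 6 were higher and 0 lower. Examples are Eef1a1 (-0.27, SE 0.06) and Eif4h (-0.59, SE 0.14). Ribosome biogenesis, where 6 of 63 measured members fell, 1 rose and 56 were not called (12 and 2 adjusted over the list alone) (median -0.16, camera adjusted p = 0.00704, adjusted p = 0.14 with an estimated correlation), and heat-shock proteins, where 4 of 41 measured members fell, 0 rose and 37 were not called (6 and 1 adjusted over the list alone) (median -0.15, camera adjusted p = 0.012, adjusted p = 0.159 with an estimated correlation), also turned, to 10 and 0 and to 5 and 0. The calls were 688 higher and 1011 lower with the values as deposited, and 2715 and 154 after median centring. The median of all genes was -0.00, -0.14 as deposited and 0.18 after median centring. Without replicate 3 of the untreated embryos 530 genes were called, and without replicates 2 or 3 of the treated embryos 533 or 568. Poly(A) controls measured 8.69 (SD 0.05) on the treated and 7.52 (SD 0.61) on the untreated arrays.

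In SCNT 1-cell embryos under amanitin Zfp352 (-3.11, SE 0.27) stood at 6.27 ± 0.28 (SD, n = 4) against 9.38 ± 0.28 (n = 3) without amanitin. Ubtfl1 (-2.16, SE 0.39), an HMG box gene of preimplantation embryos, Bambi (-1.94, SE 0.39), a TGF-beta pseudoreceptor, Bhlhe40 (-1.92, SE 0.44), a transcriptional repressor, and Psat1 (-1.90, SE 0.41) fell, and Ddit4 (1.04, SE 0.20), a stress-induced inhibitor of mTOR signaling, and Ccdc117 (1.06, SE 0.14) rose (adjusted p at most 0.0278). The test called 64 of 14916 genes (12 higher, 52 lower, 32 by at least 2-fold). Of the 2-cell stage genes 3 of 28 measured members fell, 0 rose and 25 were not called (4 and 1 adjusted over the list alone) (median -0.10, camera adjusted p = 8.49e-05). These include Zfp352 and Usp17la (-1.43, SE 0.26). Of the p53 and stress-response genes 4 of 39 measured members fell, 1 rose and 34 were not called (5 and 2 adjusted over the list alone) (median -0.18, camera adjusted p = 0.0058). Among them are Sesn1 (-1.52, SE 0.27) and Phlda3 (-1.56, SE 0.32). In the DNA methylation list 2 of 22 measured members fell, 0 rose and 20 were not called (3 and 0 adjusted over the list alone), the 2 being Gadd45g (-1.58, SE 0.32) and Gadd45b (-1.47, SE 0.35), damage-induced genes (median -0.21, camera adjusted p = 0.00207). Splicing factors (median -0.06, camera adjusted p = 0.0293, adjusted p = 0.189 with an estimated correlation) and transporters (median -0.17, camera adjusted p = 0.0281, adjusted p = 0.124 with an estimated correlation) had camera calls that end with the estimated correlation. The count rests on single arrays: without replicates 1, 3 or 4 of the untreated embryos it was 24, 40 or 19, and without replicates 1 or 2 of the treated embryos 38 or 170, and with only the compared arrays in the fit it was 6. Leaving out 1 array ended the calls of Bhlhe40 (-1.98 to -1.58) and Gadd45b (-1.54 to -1.07) in 5 of 7 omissions, of Psat1 in 4 (-1.95 to -1.81), of Phlda3 in 3 (-1.47 to -1.43), of Bambi in 2 (-1.88 to -1.87) and of Ddit4 (0.79), Gadd45g (-1.43) and Sesn1 (-1.37) in 1. Neither group holds the poly(A) controls (4.03, SD 0.09 and 0.16).

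The 2 amanitin comparisons at the 1-cell stage shared 5 higher and 7 lower genes, against 0.43 and 1.27 for independent calls. Another 8 were opposite, and the correlation over all genes was -0.03. The interaction called 359 of 14916 genes (110 higher, 249 lower, 123 by at least 2-fold), with Zfp352 (-1.88, SE 0.37), Cgrrf1 (-2.99, SE 0.55) and Btg1 (-2.57, SE 0.33) negative and Mt1 (1.88, SE 0.41) and Clcn1 (2.65, SE 0.47) positive (adjusted p at most 0.00922). Camera called 0 of the 23 lists for it, with 3 at an unadjusted p under 0.05. The calls were 346 higher and 344 lower with the values as deposited, and 58 and 1222 after median centring, and the median of all genes was -0.00, 0.12 as deposited and -0.19 after median centring. Without replicate 1 of the fertilized embryos 683 genes were called, without replicates 3 or 4 of the SCNT embryos 193 or 227, and without replicate 1 of the treated SCNT embryos 217.

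**Figure D3:**
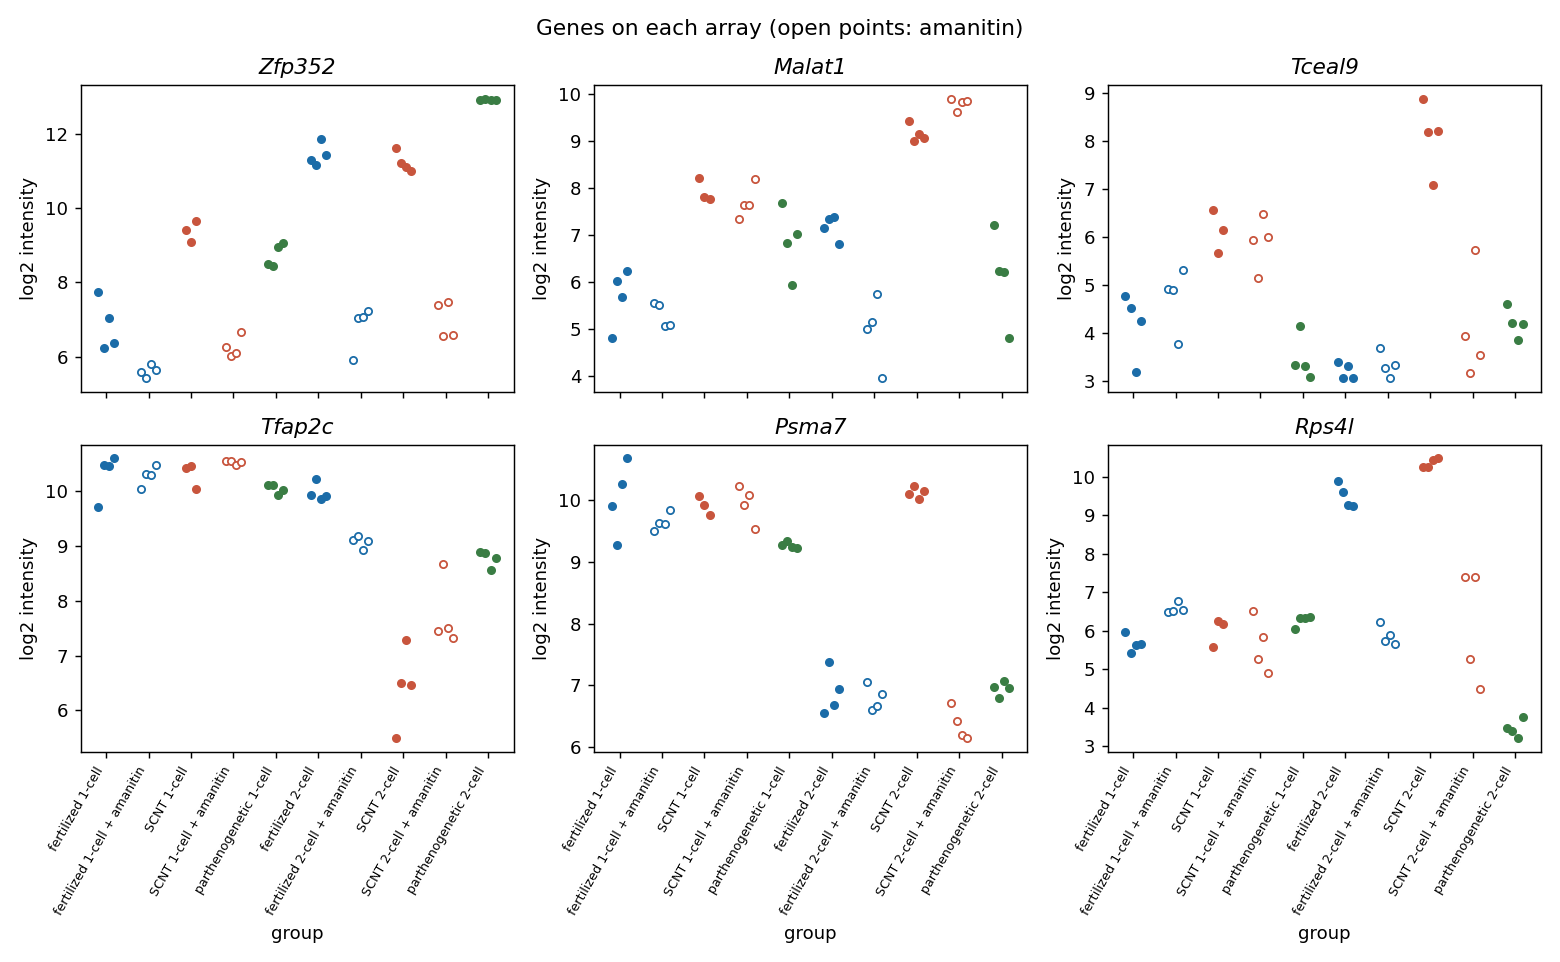
Log2 intensity of 6 genes on each of the 39 arrays (vertical axes), by group (horizontal axes), 1 point per array, with open points for amanitin. Zfp352 lies at 9.09 to 9.64 on the 3 untreated 1-cell SCNT arrays, and at 6.23 to 7.73 on the 4 fertilized 1-cell arrays.

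Between untreated SCNT and fertilized 1-cell embryos Zfp352, a zinc finger gene active at the 2-cell stage, stood at 9.38 ± 0.28 (SD, n = 3) against 6.84 ± 0.69 (n = 4). Bhlhe40 (2.35, SE 0.44), Malat1 (2.24, SE 0.38), a nuclear long noncoding RNA, Ldha (2.10, SE 0.35) and Psat1 (2.09, SE 0.41) were also higher. Lower were Bub1b (-2.09, SE 0.18), a spindle checkpoint kinase, Ptprcap (-1.96, SE 0.48) and Txnip (-1.92, SE 0.24), a thioredoxin inhibitor (adjusted p at most 0.00898). The test called 829 of 14916 genes (428 higher, 401 lower, 160 by at least 2-fold). Of the oocyte transcripts 8 of 37 measured members were lower, 0 higher and 29 not called (11 and 1 adjusted over the list alone), among the lower H1f8 (-1.33, SE 0.18), the oocyte linker histone, Zar1 (-1.11, SE 0.15), Mos (-0.87, SE 0.26), Zp3 (-0.61, SE 0.12) and Gdf9 (-0.53, SE 0.09) (median -0.05, camera adjusted p = 0.0114, adjusted p = 0.594 with an estimated correlation). Of the p53 and stress-response genes 5 of 39 measured members were higher, 1 lower and 33 not called (5 and 2 adjusted over the list alone), and the list was not called (median 0.16, camera adjusted p = 0.211). Sesn1 (1.22, SE 0.27), Egr1 (1.26, SE 0.19) and Plk2 (1.75, SE 0.40) of that list were higher, and Sall4 (-1.30, SE 0.19), a pluripotency factor, and Duxf3 (-1.17, SE 0.29), the Dux transcription factor, lower (adjusted p at most 0.00971). Xist (0.52, SE 0.20, adjusted p = 0.128), Cdkn1a (0.40, SE 0.26, adjusted p = 0.487) and Hspa1a (-0.05, SE 0.31, adjusted p = 0.972) were not called.

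Markers of cumulus and granulosa cells, the donor cell type, had 0 calls by limma among 33 measured members, 2 at an unadjusted p under 0.05, and a median of 0.02. The SCNT arrays lack the poly(A) controls that the fertilized arrays hold (mean log2 4.03, SD 0.09, against 7.52, SD 0.61). With only the compared arrays in the fit 442 genes were called. Without replicate 1 of the SCNT embryos the count was 457 and without replicate 4 it was 437. Leaving out 1 array ended the call of Mos in 6 of 7 omissions (-0.98 to -0.78), that of Ptprcap without SCNT replicate 4 (-1.90) and that of Duxf3 without SCNT replicate 1 (-0.98), and Xist was called without fertilized replicate 3 (0.67).

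In SCNT against fertilized 1-cell embryos under amanitin Ldha (3.11, SE 0.33), Malat1 (2.39, SE 0.35), Akr1c18 (2.85, SE 0.45), a steroid dehydrogenase, and Inhba (2.39, SE 0.45), the activin A subunit, were higher, and Bub1b (-2.68, SE 0.17), Pole (-2.82, SE 0.37), the catalytic subunit of DNA polymerase epsilon, Pde8a (-2.72, SE 0.29) and Ormdl1 (-2.42, SE 0.30) lower (adjusted p at most 0.000107). The test called 3214 of 14916 genes (1513 higher, 1701 lower, 682 by at least 2-fold). Xist (1.04, SE 0.18) and Mt1 (2.34, SE 0.28) were higher, and Sall4 (-2.42, SE 0.18), H1f8 (-1.87, SE 0.17), Gdf9 (-0.93, SE 0.08) and Zp3 (-0.99, SE 0.12) lower (adjusted p at most 3.35e-05). For oocyte transcripts 9 of 37 measured members were lower, 2 higher and 26 not called (9 and 2 adjusted over the list alone) (median -0.11, camera adjusted p = 0.033, adjusted p = 0.416 with an estimated correlation), but 11 higher and 9 lower with the values as deposited. For translation factors 12 of 38 measured members were higher, 4 lower and 22 not called (13 and 4 adjusted over the list alone) (median 0.11, camera adjusted p = 0.033, adjusted p = 0.378 with an estimated correlation), against 4 higher and 7 lower after median centring. Of the cumulus and granulosa markers 7 of 33 measured members were higher, 4 lower and 22 not called (7 and 4 adjusted over the list alone), and 15 had an unadjusted p under 0.05 (median 0.21, camera adjusted p = 0.323). Tnfaip6 (2.35, SE 0.36), Akr1c18 (2.85, SE 0.45) and Inhba (2.39, SE 0.45) were among the higher, and Gpx3 (-1.39, SE 0.18) and Fdx1 (-0.94, SE 0.18) among the lower. Untreated and treated comparisons, which share no array, had 267 higher and 324 lower genes in common against 43.4 and 45.7 for independent calls, and 9 opposite. The calls were 2508 higher and 1696 lower with the values as deposited, and 772 and 3049 after median centring, and the median of all genes was 0.01, 0.16 as deposited and -0.13 after median centring. Poly(A) controls were 4.03 (SD 0.16) on the SCNT and 8.69 (SD 0.05) on the fertilized arrays.

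In SCNT against fertilized 2-cell embryos Tceal9, an X-linked gene, stood at 8.09 ± 0.74 (SD, n = 4) against 3.21 ± 0.17 (n = 4), near background in fertilized embryos (6.04 or 3.56 with the low or high constant), and Bex3 (4.39, SE 0.30), also X-linked, Scube2 (4.27, SE 0.39), a secreted protein, and Col27a1 (3.85, SE 0.38), a collagen, were higher. Cltrn (-5.03, SE 0.27), the X-linked collectrin, Krt28 (-4.66, SE 0.36), Gsdmc2 (-4.16, SE 0.24), a gasdermin, Hormad1 (-3.74, SE 0.27), a protein of meiotic chromosomes, and Eif2s3y (-4.12, SE 0.31), a Y-linked translation factor, were lower (adjusted p at most 1.79e-10). Eif2s3y had a difference of 0.16 without the filter on dim probe sets, and the donor animals were female per the labels. Xist (1.23, SE 0.18) was higher, and Gdf9 (-0.74, SE 0.08) and Zp3 (-1.16, SE 0.12) lower (adjusted p at most 9.82e-07). Zfp352 (-0.21, SE 0.25, adjusted p = 0.601), Dnmt1 (0.07, SE 0.21, adjusted p = 0.844) and Eif1a (-0.24, SE 0.28, adjusted p = 0.582) were not called. The test called 4559 of 14916 genes (2133 higher, 2426 lower, 1540 by at least 2-fold).

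Of the proteasome subunits 22 of 37 measured members were higher, 0 lower and 15 not called (26 and 1 adjusted over the list alone) (median 0.60, camera adjusted p = 3.66e-11). These include Psma7 (3.24, SE 0.19), Psmb3 (2.06, SE 0.17) and Psma5 (2.02, SE 0.16). In oxidative phosphorylation 43 of 73 measured members were higher, 1 lower and 29 not called (45 and 1 adjusted over the list alone) (median 0.75, camera adjusted p = 1.93e-14). Among them are Sdhb (1.85, SE 0.16) of complex II, Ndufs7 (1.91, SE 0.17) and Ndufa12 (2.14, SE 0.23) of complex I, and Cox7a2l (1.31, SE 0.13). Among pluripotency and early lineage factors 14 of 31 measured members were lower, 1 higher and 16 not called (14 and 1 adjusted over the list alone) (median -0.40, camera adjusted p = 0.000229). Tfap2c (-3.53, SE 0.23), Tbx3 (-2.97, SE 0.22) and Sall4 (-1.63, SE 0.18) were lower and Klf4 (1.26, SE 0.15) higher. Of the p53 and stress-response genes 13 of 39 measured members were higher, 2 lower and 24 not called (13 and 2 adjusted over the list alone) (median 0.14, camera adjusted p = 0.00969). These include Ccng1 (2.06, SE 0.21), a cyclin G, and Tnfrsf10b (2.38, SE 0.36), a death receptor. For 2-cell stage genes 10 of 28 measured members were lower, 2 higher and 16 not called (10 and 2 adjusted over the list alone) (median -0.39, camera adjusted p = 0.017, adjusted p = 0.0867 with an estimated correlation). Among them are Obox3 (-2.12, SE 0.29) and Tcstv3 (-1.53, SE 0.19). For oocyte transcripts 17 of 37 measured members were lower, 4 higher and 16 not called (17 and 4 adjusted over the list alone) (median -0.23, camera adjusted p = 0.000866, adjusted p = 0.19 with an estimated correlation). Examples are Tcl1 (-1.88, SE 0.10) and Kit (-1.35, SE 0.10). Of the cytosolic ribosomal proteins 12 of 44 measured members were higher, 0 lower and 32 not called (10 and 0 adjusted over the list alone) (median 0.22, camera adjusted p = 0.00969, adjusted p = 0.51 with an estimated correlation), but 5 higher and 2 lower with the values as deposited and 2 higher and 2 lower after median centring. Of the heat-shock proteins 10 of 41 measured members were higher, 2 lower and 29 not called (11 and 3 adjusted over the list alone) (median 0.21, camera adjusted p = 0.00969, adjusted p = 0.177 with an estimated correlation), against 4 higher and 5 lower after median centring.

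Among imprinted genes, the paternally expressed Sfmbt2 (3.47, SE 0.40), Plagl1 (2.30, SE 0.38) and Impact (1.83, SE 0.41) were higher and the maternally expressed Phlda2 (-2.25, SE 0.30) and Grb10 (-1.03, SE 0.17) lower in SCNT 2-cell embryos (adjusted p at most 0.000487). Neither imprinted list was called. Of the paternally expressed 3 of 19 measured members were higher, 1 lower and 15 not called (3 and 1 adjusted over the list alone) (median -0.03, or 0.14 as deposited, mean 0.40, camera adjusted p = 0.484), and of the maternally expressed 6 of 24 measured members were lower, 5 higher and 13 not called (6 and 5 adjusted over the list alone) (mean 0.00, camera adjusted p = 0.96). Lgals3 (2.60, SE 0.26), a galectin, Anxa2 (1.93, SE 0.23) and S100a6 (2.39, SE 0.40) were higher among somatic cytoskeleton and matrix genes (adjusted p at most 8.44e-06), with median 0.07, camera adjusted p = 0.372 for that list. The calls were 2455 higher and 2097 lower as deposited, and 1637 and 2887 after median centring. The median of all genes was -0.05, with 0.05 and -0.10 in those settings. The 18S probe set measured 10.14 (SD 0.35) in SCNT and 9.50 (SD 0.21) in fertilized embryos, and the poly(A) controls 10.13 (SD 0.48) and 9.06 (SD 0.75).

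The stage change differed between SCNT and fertilized embryos for 2836 of 14916 genes (1286 higher, 1550 lower, 1451 by at least 2-fold), by the interaction (SCNT change minus fertilized change). Col27a1 (4.02, SE 0.56), Ripk3 (3.96, SE 0.56), a kinase of necroptosis, and Acadvl (3.90, SE 0.62), an enzyme of fatty acid oxidation, were positive, and Cltrn (-4.96, SE 0.39), Krt28 (-4.67, SE 0.54), Hormad1 (-4.45, SE 0.40) and Zfp352 (-2.74, SE 0.37) negative (adjusted p at most 1e-05). Among the proteasome subunits 18 of 37 measured members were positive, 0 negative and 19 not called (19 and 2 adjusted over the list alone) (median 0.70, camera adjusted p = 2.24e-11). Of the oxidative phosphorylation genes 34 of 73 measured members were positive, 0 negative and 39 not called (37 and 0 adjusted over the list alone) (median 0.81, camera adjusted p = 5.82e-15). Among pluripotency factors 10 of 31 measured members were negative, 1 positive and 20 not called (11 and 1 adjusted over the list alone) (median -0.55, camera adjusted p = 0.000434). These include Tfap2c (-3.53, SE 0.34) and Prdm14 (-2.38, SE 0.55). The calls were 1433 higher and 1392 lower with the values as deposited, and 917 and 1932 after median centring, and the median of all genes was -0.05, 0.05 as deposited and -0.13 after median centring. The untreated 1-cell SCNT arrays in this test lack the poly(A) controls (4.03, SD 0.09).

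In SCNT against fertilized 2-cell embryos under amanitin Malat1 (4.84, SE 0.35) and Gadd45g (3.03, SE 0.29) were higher, with Cep135 (3.07, SE 0.21) and Vps16 (2.87, SE 0.39). Aplf (-4.93, SE 0.22), Rbbp4 (-4.81, SE 0.29), a histone chaperone subunit, Nip7 (-4.80, SE 0.14), a ribosome biogenesis factor, and Tardbp (-4.58, SE 0.13) were lower (adjusted p at most 8.38e-08), as were Dnmt3b (-1.57, SE 0.14), a de novo DNA methyltransferase, and Gdf9 (-1.03, SE 0.08) (adjusted p at most 5.59e-12). The test called 6445 of 14916 genes (2775 higher, 3670 lower, 2920 by at least 2-fold). Of the splicing factors 52 of 63 measured members were lower, 5 higher and 6 not called (52 and 5 adjusted over the list alone) (median -1.02, camera adjusted p = 4.76e-15). Among them are Snrpd3 (-3.22, SE 0.14) and Prpf19 (-2.49, SE 0.10). Of the proteasome subunits 29 of 37 measured members were lower, 2 higher and 6 not called (30 and 2 adjusted over the list alone) (median -0.91, camera adjusted p = 1.14e-07). An example is Psmb3 (-3.17, SE 0.17). Of the cell-cycle genes 41 of 65 measured members were lower, 9 higher and 15 not called (42 and 9 adjusted over the list alone) (median -0.61, camera adjusted p = 1.14e-07). These include Cenpa (-3.43, SE 0.11) and Cks1b (-2.28, SE 0.07). Among 2-cell stage genes 15 of 28 measured members were lower, 1 higher and 12 not called (15 and 1 adjusted over the list alone) (median -0.57, camera adjusted p = 0.00596). For translation factors 21 of 38 measured members were lower, 8 higher and 9 not called (22 and 8 adjusted over the list alone) (median -0.46, camera adjusted p = 0.000495). Oxidative phosphorylation (median -0.71, camera adjusted p = 2.01e-06, adjusted p = 0.106 with an estimated correlation) and ribosome biogenesis (median -0.43, camera adjusted p = 0.00236, adjusted p = 0.0701 with an estimated correlation) lost their calls with the estimated correlation. With no array in common, the untreated and amanitin comparisons shared 527 higher and 970 lower genes against 397 and 597 for independent calls, and 1178 were opposite. The calls were 3187 higher and 3257 lower as deposited, and 2008 and 4145 after median centring. The median of all genes was -0.04, with 0.09 and -0.13 in those settings. Poly(A) controls were 11.86 (SD 0.24) on the SCNT and 8.72 (SD 0.17) on the fertilized arrays.

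**Figure D4:**
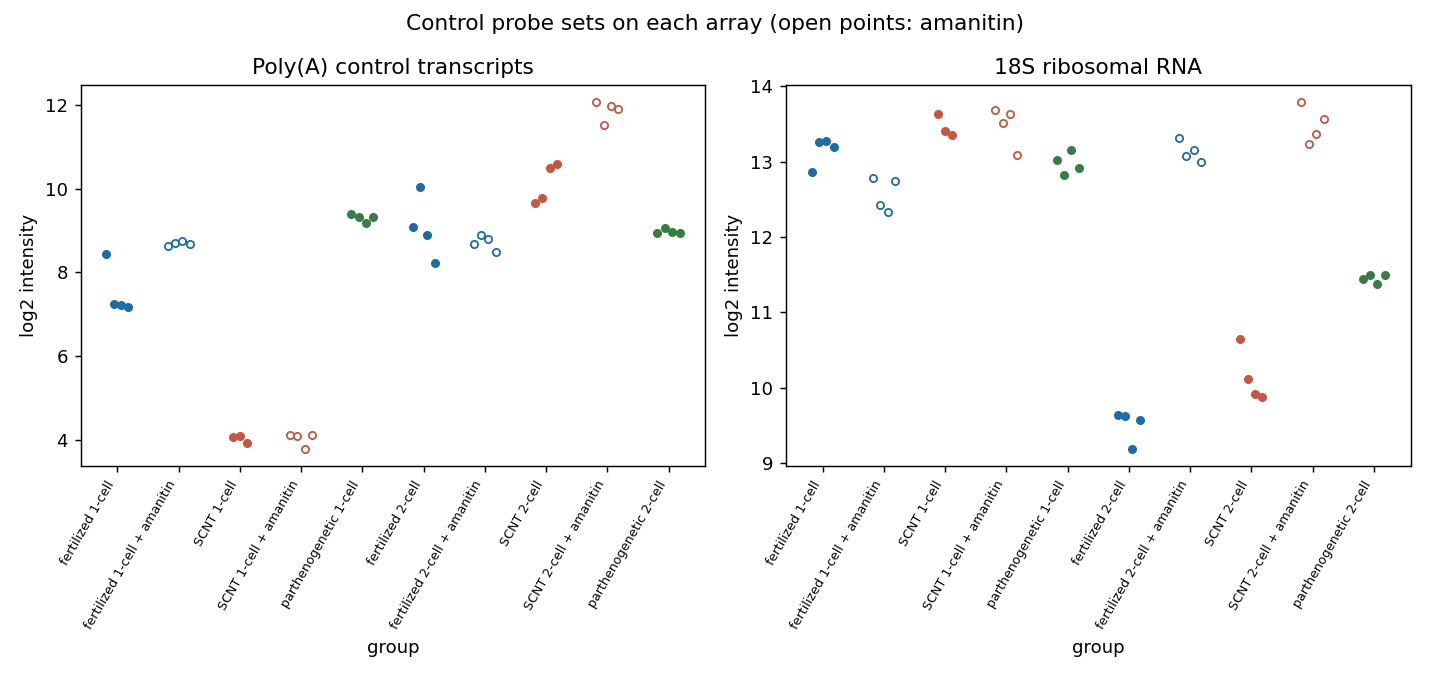
Mean log2 intensity of the poly(A) control transcripts (left) and log2 intensity of the 18S probe set (right) on each array, by group (horizontal axes), with open points for amanitin. The 7 arrays of 1-cell SCNT embryos lie at 3.80 to 4.12 for the poly(A) controls, and the other arrays at 7.18 or above.

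In parthenogenetic against fertilized 1-cell embryos Ubtfl1 (2.77, SE 0.36), Tktl1 (2.63, SE 0.32), Zfp352 (1.89, SE 0.25) and Pgm3 (2.15, SE 0.40), an enzyme of hexosamine synthesis, were higher. Txnip (-3.38, SE 0.22), Elovl5 (-2.52, SE 0.18), a fatty acid elongase, Clk1 (-2.41, SE 0.12), a splicing kinase, Gnl2 (-2.39, SE 0.23), a nucleolar GTPase, Hspa1b (-1.65, SE 0.18) and Dnmt1 (-1.47, SE 0.21) were lower (adjusted p at most 9.47e-05). The test called 3040 of 14916 genes (1620 higher, 1420 lower, 604 by at least 2-fold). Of the proteasome subunits 17 of 37 measured members were lower, 2 higher and 18 not called (18 and 3 adjusted over the list alone), with Psmb5 (-1.52, SE 0.22) (median -0.34, camera adjusted p = 3.21e-06). In ribosome biogenesis 28 of 63 measured members were lower, 4 higher and 31 not called (31 and 9 adjusted over the list alone) (median -0.35, camera adjusted p = 3.21e-06). Among them is Nmd3 (-1.84, SE 0.13). Of the heat-shock proteins 14 of 41 measured members were lower, 2 higher and 25 not called (15 and 3 adjusted over the list alone) (median -0.22, camera adjusted p = 3.21e-06). An example is Hspa8 (-2.15, SE 0.16). The calls were 1566 higher and 1915 lower with the values as deposited, and 2435 and 1072 after median centring, and the median of all genes was -0.01, -0.11 as deposited and 0.06 after median centring. Poly(A) controls were 9.30 (SD 0.09) on the parthenogenetic and 7.52 (SD 0.61) on the fertilized arrays.

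In SCNT against parthenogenetic 1-cell embryos Sgk1 (2.99, SE 0.35), Tceal9 (2.65, SE 0.45), Mt1 (2.57, SE 0.30), Mt2 (2.49, SE 0.18), Hspa1b (1.72, SE 0.19), Dnmt1 (1.32, SE 0.22) and Xist (0.93, SE 0.20) were higher. Tktl1 (-4.85, SE 0.34, but -2.61 or -3.79 with the low or high constant), Pramel18 (-2.59, SE 0.40) and Duxf3 (-2.49, SE 0.29) were lower (adjusted p at most 0.000723). The test called 2117 of 14916 genes (1044 higher, 1073 lower, 427 by at least 2-fold). In ribosome biogenesis 24 of 63 measured members were higher, 3 lower and 36 not called (26 and 4 adjusted over the list alone) (median 0.33, camera adjusted p = 1.98e-08). Of the heat-shock proteins 16 of 41 measured members were higher, 2 lower and 23 not called (18 and 4 adjusted over the list alone) (median 0.32, camera adjusted p = 2.27e-07). Of the proteasome subunits 15 of 37 measured members were higher, 2 lower and 20 not called (16 and 2 adjusted over the list alone) (median 0.29, camera adjusted p = 0.000134). Of the p53 and stress-response genes 9 of 39 measured members were higher, 0 lower and 30 not called (10 and 0 adjusted over the list alone) (median 0.29, camera adjusted p = 0.00265). The calls were 1448 higher and 1067 lower as deposited, and 769 and 1592 after median centring. The median of all genes was 0.02, with 0.12 and -0.04 in those settings. With only the compared arrays in the fit 3708 genes were called, and with array weights 3561. The SCNT arrays lack the poly(A) controls that the parthenogenetic arrays hold (4.03, SD 0.09, against 9.30, SD 0.09).

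In parthenogenetic against fertilized 2-cell embryos Rps4l, a ribosomal protein gene, stood at 3.46 ± 0.23 (SD, n = 4) against 9.50 ± 0.31 (n = 4), near background in parthenogenetic embryos (-6.96 or -4.82 with the low or high constant). Atxn10 (-4.50, SE 0.23), Tor1b (-4.46, SE 0.33), a torsin, and Tmx1 (-4.28, SE 0.33), a thioredoxin-related protein, were lower too, and Klf10 (3.49, SE 0.24), Hes1 (3.21, SE 0.37) and Insm1 (3.18, SE 0.23), transcription factors, and Psenen (3.40, SE 0.13), a gamma-secretase subunit, higher (adjusted p at most 1.51e-09). Hspa1a (2.62, SE 0.29), Hspa1b (1.93, SE 0.18), Pou5f1 (1.76, SE 0.11), the pluripotency factor OCT4, Zfp352 (1.47, SE 0.25) and Gdf9 (0.91, SE 0.08) were higher, and Eif1a (-1.07, SE 0.28), Cdkn1a (-1.06, SE 0.24) and Dnmt1 (-0.72, SE 0.21) lower (adjusted p at most 0.00335). The test called 7066 of 14916 genes (3938 higher, 3128 lower, 3473 by at least 2-fold). In ribosome biogenesis 57 of 63 measured members were lower, 0 higher and 6 not called (58 and 0 adjusted over the list alone) (median -1.20, camera adjusted p = 7.35e-23). These include Ddx21 (-3.52, SE 0.15) and Gnl3 (-2.28, SE 0.14). Of the cytosolic ribosomal proteins 37 of 44 measured members were lower, 1 higher and 6 not called (38 and 2 adjusted over the list alone) (mean -1.01, camera adjusted p = 6.22e-12). Of the translation factors 25 of 38 measured members were lower, 6 higher and 7 not called (25 and 6 adjusted over the list alone) (median -0.73, camera adjusted p = 1.93e-07). Among them is Eif3m (-2.97, SE 0.21). Of the proteasome subunits 24 of 37 measured members were lower, 8 higher and 5 not called (24 and 8 adjusted over the list alone) (median -0.90, camera adjusted p = 1.34e-06). An example is Psma6 (-3.82, SE 0.16). Of the splicing factors 37 of 63 measured members were lower, 11 higher and 15 not called (37 and 12 adjusted over the list alone) (median -0.46, camera adjusted p = 0.000242). Of the oocyte transcripts 27 of 37 measured members were higher, 4 lower and 6 not called (28 and 5 adjusted over the list alone) (median 0.89, camera adjusted p = 5.41e-08). These include Bmp15 (2.26, SE 0.12), an oocyte growth factor, and Lhx8 (1.46, SE 0.09). For 2-cell stage genes 10 of 28 measured members were higher, 5 lower and 13 not called (10 and 5 adjusted over the list alone), and the list was not called (median 0.32, camera adjusted p = 0.143). The 18S probe set measured 11.45 (SD 0.05) in parthenogenetic and 9.50 (SD 0.21) in fertilized 2-cell embryos. The calls were 4166 higher and 2948 lower with the values as deposited, and 3350 and 3400 after median centring, and the median of all genes was 0.07, 0.15 as deposited and 0.01 after median centring.

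In SCNT against parthenogenetic 2-cell embryos Rps4l (6.91, SE 0.37), 7.83 or 5.67 with the low or high constant, Nme1 (5.78, SE 0.25), a nucleoside diphosphate kinase, and Cox17 (5.45, SE 0.32), a copper chaperone, were higher, and Sox2 (-4.90, SE 0.29), Tbx3 (-4.42, SE 0.22) and Pou5f1 (-2.14, SE 0.11), pluripotency factors, Rfpl4 (-4.89, SE 0.18) and Ezhip (-4.78, SE 0.15), an inhibitor of the Polycomb complex PRC2, lower (adjusted p at most 9.14e-18). The test called 8135 of 14916 genes (3639 higher, 4496 lower, 4583 by at least 2-fold). In ribosome biogenesis 49 of 63 measured members were higher, 0 lower and 14 not called (50 and 0 adjusted over the list alone) (median 1.06, camera adjusted p = 7.18e-14). Among the proteasome subunits 32 of 37 measured members were higher, 5 lower and 0 not called (32 and 5 adjusted over the list alone) (median 1.49, camera adjusted p = 1.18e-13). Of the oxidative phosphorylation genes 55 of 73 measured members were higher, 4 lower and 14 not called (56 and 4 adjusted over the list alone) (median 1.38, camera adjusted p = 5.09e-14). Of the cytosolic ribosomal proteins 37 of 44 measured members were higher, 1 lower and 6 not called (37 and 1 adjusted over the list alone) (median 1.32, camera adjusted p = 5.9e-13). Of the oocyte transcripts 31 of 37 measured members were lower, 2 higher and 4 not called (31 and 2 adjusted over the list alone) (median -0.97, camera adjusted p = 3.38e-10). Of the 2-cell stage genes 15 of 28 measured members were lower, 4 higher and 9 not called (17 and 5 adjusted over the list alone) (median -0.76, camera adjusted p = 0.00463). The 18S probe set measured 10.14 (SD 0.35) in SCNT and 11.45 (SD 0.05) in parthenogenetic embryos, and the poly(A) controls 10.13 (SD 0.48) and 8.97 (SD 0.06).

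Over the 18 comparisons camera called 0 results for glycolysis and glucose transport (lowest adjusted p 0.134, 2 at an unadjusted p under 0.05), cumulus and granulosa markers (0.188), somatic cytoskeleton and matrix genes (0.0766, 3 unadjusted), spermatid and sperm transcripts (0.153), blood and immune cell markers (0.439), histone modifiers and remodellers (0.0529, 3 unadjusted), paternally expressed imprinted genes (0.378) and maternally expressed imprinted genes (0.251), with 0 unadjusted for the others. Of 414 list tests 121 were called with the preset correlation, and 89 of these also with the estimated one.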

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

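The tests of RNA processing, of donor cell RNA, of the normalization, of the mean of 2-cell stage genes and of precision in bright genes were chosen after the results they bear on were seen. Within groups of 4 arrays, the lowest or highest array was compared with the nearest other by Dixon's ratio, for list means, control measures and the genes fixed beforehand. Of 396 groups of values, 27 held an array far from the others (9 for lists, 8 for controls and 10 for genes), where chance alone gives about 1 in 20 groups, or 19.8. Values are mean log2 signals or log2 ratios, with the range of the other 3 arrays.

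Among fertilized 1-cell embryos, replicate 1 had splicing factors at 9.47 (9.61 to 9.62), p53 and stress-response genes at 6.87 (6.97 to 6.99), an Actb 3' over 5' ratio of 2.59 (1.71 to 1.74) and poly(A) controls at 8.43 (7.18 to 7.24). Replicate 4 had Dnmt3b at 8.72 (9.16 to 9.24). With amanitin, replicate 1 had a Gapdh ratio of 2.58 (2.43 to 2.45) and a poly(A) minus hybridization control difference of -1.26 (-0.84 to -0.76). Among fertilized 2-cell embryos the 18S probe set of replicate 3 was at 9.19 (9.57 to 9.64). With amanitin, replicate 1 had an Actb ratio of 2.55 (2.05 to 2.13) and Zfp352 at 5.92 (7.03 to 7.22), and replicate 3 had Actb at 10.86 (10.67 to 10.70).

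Among parthenogenetic 1-cell embryos replicate 1 had oocyte transcripts at 10.42 (10.49 to 10.50). Among the 2-cell ones replicate 2 had RNA polymerase II genes at 9.18 (9.21 in the others), and replicate 4 a Gapdh ratio of 2.24 (2.65 to 2.70) and Pou5f1 at 11.16 (10.73 to 10.78). SCNT 1-cell embryos with amanitin had oocyte transcripts at 10.47 in replicate 4 (10.63 to 10.66), poly(A) controls at 3.80 in replicate 3 (4.09 to 4.12), Pou5f1 at 10.30 in replicate 1 (10.44 to 10.45) and Dnmt3b at 9.59 in replicate 2 (8.90 to 8.93). In SCNT 2-cell embryos replicate 1 had DNA methylation genes at 6.89 (7.02 at most in the others) and maternally expressed imprinted genes at 6.65 (6.41 to 6.43). With amanitin, DNA methylation genes were at 6.62 (7.02 to 7.06) and paternally expressed imprinted genes at 6.25 (6.45 to 6.48) in replicate 4. Replicate 3 had Eif1a at 4.48 (5.86 to 6.02), Xist at 7.85 (6.96 to 7.10) and Prm1 at 3.89 (5.37 to 5.61), and replicate 1 had Mos at 4.01 (5.03 to 5.12).

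Interaction tests by limma called differences between SCNT and fertilized embryos in the amanitin effect for 359 genes at the 1-cell and 5807 at the 2-cell stage, and in the stage change for 2836. Among the control transcripts, which the gene comparisons leave aside, the Dap poly(A) control had a mean intensity of 8720 (SD 1030) in SCNT 2-cell embryos with amanitin, against 3070 (SD 867) without. Hybridization controls rose on the same arrays, to 10.88 (SD 0.19) from 9.58 (SD 0.15), and poly(A) minus hybridization controls moved by 0.43 (exact permutation p = 0.114, 4 arrays each).

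SCNT and fertilized 1-cell embryos differed in 829 genes. Over untreated and treated 1-cell arrays together, the poly(A) controls differed by -4.07 log2 units between SCNT and fertilized embryos (highest SCNT array 4.12, lowest fertilized array 7.18), so that separate RNA processing and origin cannot be told apart. RNA of the cumulus donor cell is a hypothesis: the median of 33 markers was at percentile 98.5 of 10000 random lists under amanitin (0.21) and at 64.5 without (0.02), and 24 of the 33 are expressed above the overall median in fertilized 1-cell embryos. Under amanitin 7 were higher, with Akr1c18 (2.85), and 4 lower, with Gpx3 (-1.39), so the markers move apart and donor RNA cannot be told apart from other effects of origin or from medium, which stay open, untested. The markers with the highest intensities in treated SCNT embryos, Fdx1 (10.05), Nr5a2 (9.02) and Hsd17b7 (8.25), had differences of -0.94, 0.17 and -0.24, but intensities of different probe sets do not rank abundance.

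Parthenogenetic and fertilized 2-cell embryos differed in 7066 genes. The quantile normalization as the cause is argued against by 7114 calls with the values as deposited, of which 6765 were shared. An earlier point of the change from 1-cell to 2-cell is a candidate explanation: of genes chosen in SCNT embryos, the 2911 that rose had a median of -0.83 (SD 0.03 over arrays) and the 3481 that fell 0.70 (SD 0.03), a difference of 1.54 (score of fallen minus risen genes 0.12, SD 0.06, against -1.44, SD 0.11, exact permutation p = 0.0286, 4 arrays each). The mean of the 2-cell stage genes goes against it, at 10.24 (SD 0.08) in parthenogenetic and 9.81 (SD 0.06) in fertilized embryos (exact permutation p = 0.0286, adjusted p = 0.0346), but members went both ways, 10 higher and 5 lower of 28 (camera adjusted p = 0.143), so it stays open. Whether collection times or parental genomes set this apart was not tested, and both stay open.

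The amanitin effect differed between SCNT and fertilized 2-cell embryos in 5807 genes. The quantile normalization is argued against by 5576 calls with the values as deposited, 5209 of them shared. Weaker signal on the treated SCNT arrays cannot be told apart from origin: 67.5% of the 3729 brightest genes were called against 38.9% of all, which met the bound set for excluding it, but that bound was wrong, as bright genes are measured more precisely (median SE 0.18 against 0.33). Less embryo RNA beside the controls stays open, as poly(A) minus hybridization controls averaged 0.98 (SD 0.18) on the treated SCNT arrays and -1.33 (SD 0.18) on the treated fertilized ones. So do origin and medium, untested.

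With only the compared arrays in the fit, the splits do not exclude chance for SCNT against fertilized 1-cell embryos: 2 of the 35 splits of the arrays gave as many calls, with 442 for the real split and 548 for fertilized replicates 2, 3 and 4 against the rest. Chance is argued against by the amanitin comparison of the same origins, which shares no array and repeated 267 higher and 324 lower of the 829 calls, against 43.4 and 45.7 for independent calls, with 9 opposite. The splits do not exclude chance for amanitin in SCNT 1-cell embryos, again 2 of 35, with 6 calls against 61 for treated replicates 1, 3 and 4 against the rest. In the 13 other group comparisons the real split alone gave as many, 1 of 35, the least possible, unadjusted. Real counts, with the highest of the other splits, were as follows at the 1-cell stage: 3708 and 0 for SCNT against parthenogenetic, 3218 and 1 for parthenogenetic against fertilized, 827 and 0 for amanitin in fertilized, and 3838 and 0 for SCNT against fertilized embryos under amanitin. At the 2-cell stage they were 4696 and 0 for SCNT against fertilized, 8010 and 1 for SCNT against parthenogenetic, 7135 and 1 for parthenogenetic against fertilized, 9526 and 0 for amanitin in fertilized, 9727 and 0 for amanitin in SCNT, and 5344 and 0 for SCNT against fertilized embryos under amanitin. Between the stages they were 8798 and 0 in fertilized, 9236 and 0 in SCNT, and 7693 and 0 in parthenogenetic embryos. For the interactions, 1 of 100 arrangements of residuals, the real one, gave as many calls: 317 and 0 for amanitin at the 1-cell stage, 5235 and 2897 for amanitin at the 2-cell stage, and 2788 and 2225 for the stage change. Other splits and permuted residuals hold any real difference, and why other arrangements of the last 2 gave high counts was not tested.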

How the results depend on the processing

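Leaving out 2 arrays that stood apart was chosen after seeing the data. Apart from the single-array omissions, 13 of the 18 counts of called genes stayed within 1.5 times of the reported count under each alternative run. The exceptions were counts at the 1-cell stage, and the cause was not tested. With array weights, 1410 genes differed between SCNT and fertilized, 3561 between SCNT and parthenogenetic 1-cell embryos, and the amanitin effect counted 2051 genes in fertilized and 159 in SCNT 1-cell embryos, with 1054 for the 1-cell amanitin interaction. With only the compared arrays in the fit, the counts were 442 for SCNT against fertilized, 3708 for SCNT against parthenogenetic and 6 for amanitin in SCNT 1-cell embryos. The amanitin effect in fertilized 1-cell embryos counted 1699 genes with the values as deposited, 2869 after median centring and 559 with the mean of a gene's probe sets, and its interaction with origin 690, 1280 and 184. Without the 2 arrays that stood apart that interaction called 611 genes. With a 4-fold threshold the mean difference of transcription-dependent genes was -0.12, against -0.06 as reported.

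Leaving out 1 array at a time gave 437 to 1085 calls for SCNT against fertilized, 1434 to 1818 for SCNT against parthenogenetic, and 2438 to 3255 for parthenogenetic against fertilized 1-cell embryos. For amanitin at the 1-cell stage it gave 530 to 1264 in fertilized and 19 to 170 in SCNT embryos, and 193 to 683 for the interaction. The low ends came without SCNT replicate 4 (437 and 19), fertilized replicate 3 (530) and SCNT replicate 3 (193), and the high ends without fertilized replicate 1 (1085, 1264 and 683) and SCNT amanitin replicate 2 (170). At the 2-cell stage the ranges were 4083 to 4266 for SCNT against fertilized, 7708 to 7883 for SCNT against parthenogenetic, 6629 to 6840 for parthenogenetic against fertilized, 9228 to 9343 and 10003 to 10185 for amanitin in fertilized and SCNT embryos, and 5574 to 5798 for their interaction. Under amanitin they were 2658 to 2957 and 6089 to 6361 for SCNT against fertilized embryos at the 2 stages. Between the stages they were 8622 to 8714 in fertilized, 8520 to 8818 in SCNT and 6890 to 7102 in parthenogenetic embryos, and 2428 to 2957 for the stage interaction.

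Of 290 named differences, 1 reversed over 5816 combinations: Eif2s3y (2-cell SCNT minus fertilized) had 0.16 without a filter, cause untested. Some genes with unstable calls were left out, which can lower these counts. Calls ended for 12 with only the compared arrays, 4 with the mean of a gene's probe sets, 4 with the constant at the 5th percentile, 3 after median centring, 1 without the trend and 2 without the 2 arrays that stood apart, and 12 differences changed their call in some omission of an array. A replicate block, which treats arrays of the same number as paired, gave 778 calls for SCNT against fertilized 1-cell embryos and 350 for the 1-cell amanitin interaction, and 1 named gene lost its call. Of 414 list tests, 32 lost and 1 gained a call with the estimated correlation, 18 and 9 with the values as deposited, and 1 and 2 with the block.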

Other observations

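The comparison of the stages within amanitin-treated embryos was chosen after the data were seen, and the delay in SCNT embryos was tested because list results had raised it. From the 1-cell to the 2-cell stage under amanitin limma called 6051 genes in fertilized embryos (3212 higher, 2839 lower) and 8262 in SCNT embryos (3823 higher, 4439 lower). The origins shared 2085 lower genes, against 844.9 for independent calls, and 1817 higher ones, against 823.2, while 681 were opposite. The list of proteasome subunits fell in both fertilized (median -1.26, camera adjusted p = 1.64e-09) and SCNT embryos (median -1.98, camera adjusted p = 1.5e-12). Splicing factors fell in SCNT embryos (median -1.65, camera adjusted p = 8.73e-16), and in fertilized embryos had a call that ends with the estimated correlation (median -0.17, camera adjusted p = 0.00289, adjusted p = 0.0881 with an estimated correlation). Oocyte transcripts fell in fertilized embryos (median -0.56, camera adjusted p = 7.02e-08), and their call in SCNT embryos ended likewise (median -0.69, camera adjusted p = 9.34e-05, adjusted p = 0.113 with an estimated correlation). The treated SCNT arrays lack the poly(A) controls at the 1-cell stage (4.03, SD 0.16) and hold them at the 2-cell stage (11.86, SD 0.24), so stage and RNA processing cannot be separated there.

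A hypothesis was that SCNT 2-cell embryos may also stand at an earlier point of the change from 1-cell to 2-cell than fertilized ones. Of genes chosen in parthenogenetic embryos, the 1686 that rose had a median SCNT minus fertilized difference of -0.13 (SD 0.03 over arrays) and the 2220 that fell 0.10 (SD 0.04), a difference of 0.23. The score of fallen minus risen genes was -1.77 (SD 0.00) in SCNT and -2.07 (SD 0.06) in fertilized embryos (exact permutation p = 0.0286, 4 arrays each). Both medians have the sign of a delay but fall short of the 0.2 set for it, so a small delay and other differences of origin cannot be told apart.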
